A study of Homo sapiens with 18 samples.

How the data were processed

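The samples were 18 liver biopsies of 9 patients with hepatitis C virus infection, 9 taken before (PRE) and 9 at the end (EOT) of all-oral antiviral treatment. Per the labels' protocols, RNA was extracted with the RNeasy 96 kit, amplified and labelled with the Ovation Pico WTA system and hybridised to Affymetrix Human Gene 2.0 ST arrays. The deposited table holds log2 expression values that the authors computed, 1 for each of 53617 probe sets and each array. The log2 scale was judged from the values, which spanned 0.877 to 13.25. The summarisation, background correction and normalization are not given in the sources used here. The deposited arrays were not brought to one distribution: array medians ranged from 2.74 to 4.47 at PRE and from 3.18 to 4.27 at EOT.

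Probe sets were named through the platform annotation given with the data, with symbols checked by gene identifier. All 16098 named probe sets matched, 0 symbols changed, 0 probe sets carried several symbols, and 37519 were not named here. Of the 14884 genes tested, 779 had more than 1 named probe set, and for these the probe set with the highest mean over the 18 arrays was used. No filter on dim probe sets was applied.

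The pairing was taken from the label that names each biopsy's mate, and the pair was a block in the fits unless a setting named below says otherwise. Mates' deviations from their group means correlated by 0.109 to 0.410 (mean 0.234), against a mean of -0.0292 for other PRE and EOT arrays. The best match was the mate for 7 of 9 PRE and 8 of 9 EOT arrays, and 0 of 9 pairs disagreed in a check for mixed-up samples.

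Changes are EOT minus PRE. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, pair and time in the model), with Benjamini-Hochberg adjustment over 14884 genes and a threshold of 0.05. With the deposited values, limma's prior degrees of freedom were 206 against 8 residual ones. With quantile-normalized values they were 6.37. Gene lists were compared with all other genes by camera (preset inter-gene correlation 0.01, adjusted over 21 lists), and by an exact sign-flip test of the list mean over 9 pairs. The spread of the interferon score was tested by exact swaps of PRE and EOT within pairs after centring each group. Errors are SDs over pairs for changes and over biopsies for levels. Figures were drawn with matplotlib 3.10.9.

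The design, the main settings, the other settings to be tried, the 23 gene lists and the rule for named genes were fixed before the data were examined. The lists cover interferon-stimulated genes, interferon-gamma-induced genes, class I and class II antigen presentation, interferon ligands, interferon receptors and signal transducers, markers of the cell types of a liver biopsy (T and NK, B and plasma, macrophage, stellate, bile duct, endothelial, hepatocyte and blood cells, and fat, muscle and skin), bile acids, drug metabolism, cholesterol, fatty acids, cell division, endoplasmic reticulum stress, acute phase and NF-kB, and immediate early genes. Lists with fewer than 3 named members were not tested. The rule named the 10 largest falls and the 10 largest rises past the threshold (all of them where fewer passed), up to 4 members of each list with the smallest p, and members of the interferon ligand and receptor lists. Part of the list members that this rule allows are printed, a choice made after their values were seen. Outside the rule, UPP2, HCP5, LAP3, RNF213, SAMHD1, ACSM3, FREM2 and PHGDH were likewise chosen after their values were seen.

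The fit was tested on 14884 simulated genes, of which 67 changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale. As deposited, it found 4.48% of changes of 0.5 on the log2 scale, 97.0% of changes of 1 and 100% of changes of 2, and it called 9 of 14684 unchanged genes. After quantile normalization it found 71.6%, 100% and 100%, and called 6 of 14684. Noise was drawn independently for each gene, with the spread of the quantile-normalized fit, and array levels kept their real arrangement over PRE and EOT. The simulation therefore does not show how many false calls the deposited fit makes when genes vary together.

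The other settings fixed in advance were no pair block, the pair as a random effect, a brightness filter (7442 genes kept), all probe sets, the mean of a gene's probe sets, quantile normalization, subtraction of array medians, an intensity trend with robust variances, array weights, an adjusted p of 0.10, a minimum change of 1.5-fold, estimated inter-gene correlations, limma's rotation test fry, the median over list members, and leaving out each pair. Added after seeing the data were the array median as a covariate, the 5 pairs whose array medians differ by less than 0.5, quantile normalization with estimated correlations, and the spread with array medians subtracted. Cirrhosis status was not analysed here. The unnamed probe sets entered only the alternative over all probe sets and a separate count.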

Results

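Gene expression was measured with Affymetrix Human Gene 2.0 ST arrays, which carry probe sets along whole transcripts, in liver biopsies of patients with hepatitis C virus infection who took an all-oral course of direct-acting antivirals. Each of 9 patients gave 1 biopsy before treatment (PRE, within 1.2 years of its start) and 1 at the end of treatment (EOT, within 5 days of its completion), so the 18 arrays form 9 pairs. The series' title asks how cirrhosis bears on the liver's own interferons during treatment. Cirrhosis status was not analysed here, and every comparison below is EOT against PRE within patients. Array data have no read depth, and the number of arrays limits the precision.

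The deposited log2 values spanned 0.877 to 13.25, and the arrays differed in overall level. The median over all probe sets was 3.63 ± 0.585 at PRE (SD, n = 9) and 3.70 ± 0.395 at EOT (SD, n = 9). Within pairs, the EOT median minus the PRE median ran from -1.11 in pair 4 to 0.83 in pair 2. The first principal component of the genes held 73.7% of the variance of the deposited values, and its correlation with the array median had a size of 0.997 across the 18 arrays. Values after quantile normalization are therefore given beside the deposited ones where that normalization changes a call.

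The main question was which genes differ between the untreated, infected liver and the liver at the end of treatment. Interferon-driven genes were lower at EOT. CXCL10 (probe set 16977052), a chemokine that draws activated T cells, fell from 10.13 ± 0.73 to 7.14 ± 1.17, a log2 change of -2.99 ± 1.32 (SD over 9 pairs), or 7.92-fold, and was lower in 9 of 9 pairs. ISG15 (probe set 16657594), a ubiquitin-like modifier, fell from 9.38 ± 0.83 to 7.13 ± 0.37, a log2 change of -2.25 ± 0.77 (SD, 9 of 9 pairs lower). Few genes were higher at EOT, and the largest rise was 1.19 ± 1.42 on the log2 scale (SD over 9 pairs), for the long noncoding RNA LINC01093.

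In limma's paired fit of 14884 genes, 30 genes passed a Benjamini-Hochberg adjusted p of 0.05, with 26 lower and 4 higher at EOT. With 206 prior degrees of freedom against 8 residual ones, this fit gave the called genes nearly one standard error. It was 0.210 for IRF9 (SD over pairs 0.39) and 0.228 for LINC01093 (SD over pairs 1.42). The deposited p-values therefore say little about a gene's own spread over pairs. Of the 26 lower genes, 20 belonged to the list of interferon-stimulated genes and 4 to that of genes induced by interferon-gamma. The remaining 2 were UPP2, a uridine phosphorylase, with a log2 change of -1.18 ± 1.40, and HCP5, a noncoding gene of the class I antigen region, with -0.86 ± 0.42 (SD over 9 pairs). They are named because they were the only lower genes outside both lists, and were chosen after their values were seen. After quantile normalization UPP2 was at -1.33 ± 1.37, lower in 8 of 9 pairs, and did not pass (adjusted p = 0.139, limma; 0.437 at most over its alternatives). HCP5 passed there (-0.97 ± 0.54, adjusted p = 0.00594, limma), and its adjusted p reached 1.00 over its alternatives.

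Among the 10 largest falls, 7 genes besides CXCL10, CXCL11 and CXCL9 were members of the interferon-stimulated list. IFI44L changed by -2.25 ± 1.10, DDX60, a helicase of antiviral defence, by -1.93 ± 0.60, and OASL, a relative of the oligoadenylate synthetases, by -1.92 ± 1.02 (log2, SD over 9 pairs). HERC5, the ligase that attaches ISG15 to proteins, changed by -1.86 ± 0.89, IFI44 by -1.73 ± 0.70 and IFIT1, which binds viral RNA, by -1.71 ± 0.99. CXCL11 and CXCL9, which share the receptor of CXCL10, changed by -1.88 ± 0.82 and -1.78 ± 1.40. DDX60, OASL, HERC5, IFI44 and CXCL11 were lower in 9 of 9 pairs, and IFI44L, IFIT1 and CXCL9 in 8. After quantile normalization all 10 genes passed again, with log2 changes from -3.11 for CXCL10 to -1.82 for IFIT1. CXCL10 did not pass with an intensity trend and robust variances (adjusted p = 0.0530, limma, the highest over its alternatives). CXCL9 did not pass without pair 4 (adjusted p = 0.308, limma), and its adjusted p reached 0.704 over its alternatives. IFIT1 did not pass without pair 4 either (adjusted p = 0.0540, the highest over its alternatives).

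**Figure D1:**
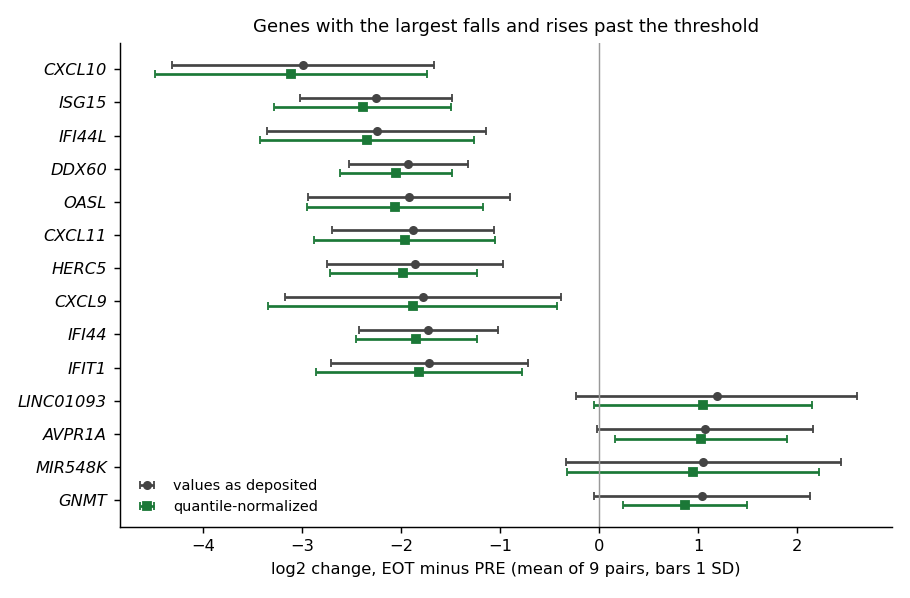
Mean log2 change at EOT against PRE of the 10 genes with the largest falls and the 4 that rose, with bars of 1 SD over 9 pairs, for values as deposited (circles) and after quantile normalization (squares). CXCL10 lies at -2.99 as deposited and -3.11 after normalization, and the bars of the falling genes stay below 0.

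The 4 higher genes were LINC01093, AVPR1A, MIR548K and GNMT. AVPR1A, a vasopressin receptor, changed by 1.07 ± 1.09, the microRNA gene MIR548K by 1.05 ± 1.38, and GNMT, a liver enzyme that methylates glycine, by 1.04 ± 1.09 (log2, SD over 9 pairs). They were higher in 8, 5 and 7 of the 9 pairs, and LINC01093 in 7. After quantile normalization GNMT passed (0.87 ± 0.63, adjusted p = 0.0351, limma). LINC01093 (1.05 ± 1.10, adjusted p = 0.154), AVPR1A (1.03 ± 0.87, adjusted p = 0.0654) and MIR548K (0.95 ± 1.28, adjusted p = 0.306) did not. Over their alternatives the adjusted p of each of the 4 genes reached at least 0.772.

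The count of changed genes moved with the scaling. Quantile normalization gave 79 genes, 62 lower and 17 higher, of which 26 had also passed in the same direction as deposited. The share of lower genes among those called was 86.7% as deposited, 78.5% after quantile normalization and 73.1% with array medians subtracted. The median change of all genes was 0.08 as deposited and -0.01 after quantile normalization. Without pair 4, whose array medians differed most, 12 genes passed as deposited and 69 after quantile normalization. The fit without the pair as a block called 17 genes, all lower.

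The gene lists ask whether groups of genes moved together. The 41 measured interferon-stimulated genes had a mean log2 change of -0.95 ± 0.52 (SD over 9 pairs) and were lower in 9 of 9 pairs (exact 2-sided sign-flip test, p = 0.00391, the smallest that 9 pairs can give, adjusted p = 0.0410 over 21 lists). Of these members 20 fell and 21 did not pass over all genes, and 33 fell when adjusted over the list alone. The 11 measured genes induced by interferon-gamma had a mean change of -0.87 ± 0.51, again lower in 9 of 9 pairs (exact sign-flip test, p = 0.00391, adjusted p = 0.0410). Their median over members was nearer to no change, at -0.45, and 7 of the 11 did not pass over all genes. In this list CXCL10, CXCL11, CXCL9 and GBP4, a guanylate-binding protein, fell, and 5 members fell when adjusted over the list alone. GBP4 changed by -0.84 ± 0.56 with an adjusted p of 0.0495 (limma), which reached 1.00 over its alternatives. Both lists passed limma's camera test against all other genes, and kept that call with an estimated correlation (adjusted p = 0.000316 for each). After quantile normalization their mean changes were -1.07 ± 0.41 and -0.98 ± 0.45, with 31 and 6 members lower over all genes, and 41 and 9 when adjusted over the list alone.

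**Figure D2:**
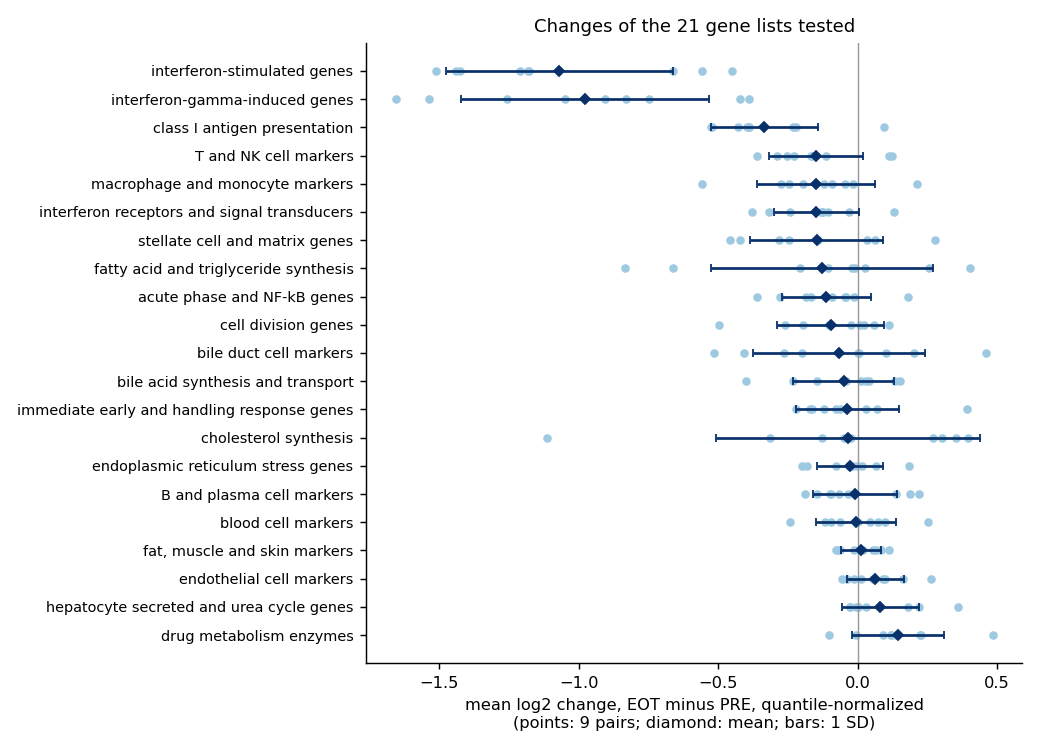
Mean log2 change at EOT against PRE of each of the 21 gene lists after quantile normalization, with 1 point for each of the 9 pairs and a diamond with bars of 1 SD. The interferon-stimulated and interferon-gamma-induced lists lie at -1.07 and -0.98, below 0 in 9 of 9 pairs, and the other lists lie between -0.33 and 0.14.

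The measured genes of antigen presentation and of interferon sensing moved less. Only 4 of 18 class I list members, none of them an HLA gene, and 13 of 20 receptor and transducer members had a named probe set. The unmeasured members may differ. The 4 measured class I antigen presentation genes had a mean change of -0.22 ± 0.37 (SD, lower in 6 of 9 pairs), and the list passed camera with the preset correlation (adjusted p = 0.000380) but not with an estimated one (adjusted p = 0.263 with an estimated correlation). After quantile normalization the mean was -0.33 ± 0.19, lower in 8 of 9 pairs. There the list passed camera with the preset correlation (adjusted p = 0.000225) and fry (adjusted p = 0.00321). It did not pass camera with an estimated correlation (adjusted p = 0.0563) or the exact sign-flip test after adjustment (p = 0.00781, adjusted p = 0.0547). Its member B2M, the light chain of class I molecules, changed by -0.59 ± 0.23 in 9 of 9 pairs, which did not pass over all genes as deposited, and passed after quantile normalization (-0.71 ± 0.28, adjusted p = 0.00136, limma; up to 1.00 over its alternatives). B2M was the 1 member lower when adjusted over the list alone. TAPBP changed by -0.17 ± 0.37, ERAP2 by -0.17 ± 0.74 and ERAP1 by 0.03 ± 0.43, none past the test. The value of ERAP1 was -0.08 after quantile normalization, and that of ERAP2 ran from -0.33 without pair 3 to -0.07 without pair 5. Over all its alternatives ERAP2 reached -0.67, and it passed in none of them.

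None of the 13 measured interferon receptors and signal transducers passed as deposited, over all genes or adjusted over the list alone. Their mean change was -0.04 ± 0.48 (SD, lower in 6 of 9 pairs), which passed camera with the preset correlation (adjusted p = 0.0168) and not otherwise (adjusted p = 0.827 with an estimated correlation). After quantile normalization it was -0.15 ± 0.15, lower in 8 of 9 pairs. As deposited it ran from -0.14 to 0.06 with 1 pair left out, and camera did not pass without pair 1 (adjusted p = 0.0912) or pair 8 (0.0723). TLR3, a sensor of double-stranded RNA, changed by -0.38 ± 0.41 and the kinase JAK2 by -0.35 ± 0.78. After quantile normalization both passed, at -0.51 ± 0.30 (adjusted p = 0.0320, limma) and -0.47 ± 0.31 (adjusted p = 0.0477, limma), and the adjusted p of each reached 1.00 over its alternatives. The adaptor MAVS was at 0.44 ± 0.57, the DNA sensor CGAS at -0.35 ± 0.54, the interferon-gamma receptor chains IFNGR1 and IFNGR2 at -0.13 ± 0.54 and -0.05 ± 0.51, and the kinases JAK1 and TYK2 at 0.15 ± 0.36 and 0.14 ± 0.52. IFNGR1 ran from -0.28 without pair 2 to -0.05 without pair 4, and IFNGR2 was at 0.03 without pair 4 or pair 10. The interferon ligands and the class II antigen presentation genes were not tested, because 0 of 21 and 1 of 14 members had a named probe set.

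Markers of the cell types that a biopsy can hold had smaller changes than the interferon lists. With 9 pairs none of their members passed over all genes, as deposited or after quantile normalization. The 24 T and NK cell markers had a mean change of -0.06 ± 0.50 as deposited and -0.15 ± 0.17 after quantile normalization (SD over 9 pairs). The 17 macrophage and monocyte markers stood at -0.04 ± 0.48 and -0.15 ± 0.21, and the 15 stellate cell and matrix genes at -0.05 ± 0.69, with a median over members of 0.004, and -0.15 ± 0.24. As deposited all 3 lists passed camera as lower with the preset correlation (adjusted p = 0.000349, 0.00629 and 0.00629), and none with an estimated one (adjusted p = 0.827 for each with an estimated correlation). After quantile normalization all 3 passed again with the preset correlation (adjusted p = 0.000681, 0.000878 and 0.00815, camera), and none with an estimated one. Endothelial markers (12 measured) were at 0.18 ± 0.54 as deposited and 0.06 ± 0.10 after quantile normalization, and the 20 hepatocyte secreted and urea cycle genes at 0.20 ± 0.39 and 0.08 ± 0.14. Both passed camera as higher as deposited (adjusted p = 0.0462 and 0.00513), again not with an estimated correlation (adjusted p = 0.827 for each). After quantile normalization the hepatocyte list passed with the preset correlation (adjusted p = 0.0339, camera) but not otherwise (adjusted p = 0.586 with an estimated correlation), and the endothelial list did not (adjusted p = 0.131), a call that was lost in 14 of its 19 alternatives. With 1 pair left out, the deposited means of the T and NK, macrophage and stellate lists ran up to 0.05, 0.06 and 0.10. That of the endothelial list ran from 0.09 to 0.30. The macrophage list did not pass camera without pair 1 (adjusted p = 0.0582) or pair 8 (0.119), nor the stellate list without pair 1 (0.0912) or pair 6 (0.0880). Adjusted over the list alone, 1 of the hepatocyte genes was higher as deposited and no member of the other 4 lists passed. After quantile normalization 2 T and NK cell markers and 5 macrophage markers were lower by that count, and 0 hepatocyte genes were higher.

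Single markers went both ways. CCL5, a T cell chemokine, was at -0.42 ± 0.44, CD2, a T cell surface protein, at -0.41 ± 0.62, the lysozyme gene LYZ at -0.33 ± 0.61 and TYROBP, a myeloid adaptor, at -0.18 ± 0.36 (log2, SD over 9 pairs). LAG3, an inhibitory receptor of T cells, was at 0.33 ± 0.85 and CD14, a monocyte receptor, at 0.27 ± 0.66, or 0.09 without pair 8. LAG3 ran from 0.17 without pair 3 to 0.54 without pair 4. The matrix genes EFEMP1 and TIMP1 were at -0.56 ± 1.25 and -0.20 ± 0.53, and EFEMP1 was at -0.21 without pair 4. Among sinusoidal endothelial genes STAB2 was at 0.38 ± 0.58, KDR at 0.38 ± 0.71 and LYVE1 at 0.37 ± 0.73. PCK1, the gatekeeper enzyme of glucose synthesis, was at 0.79 ± 1.30 and HPX, a haem-binding plasma protein, at 0.48 ± 0.56. PCK1 passed over all genes without pair 6 (adjusted p = 0.0495, limma). Markers of bile duct cells (0.02 ± 0.59), B and plasma cells (0.05 ± 0.57), blood cells (0.06 ± 0.58) and fat, muscle and skin (0.07 ± 0.54) did not pass camera as deposited, and none of their members passed over all genes or adjusted over the list alone. The bile duct list passed as lower relative to other genes without pair 4 (adjusted p = 0.0445, camera) and without pair 10 (adjusted p = 0.0239). Their camera test pointed to lower values while the mean and the median over members lay above 0, beside a median of 0.08 over all genes. After quantile normalization the means were -0.07 ± 0.31, -0.01 ± 0.15, -0.01 ± 0.14 and 0.01 ± 0.07. KRT23, a bile duct keratin, was at -0.32 ± 0.58, PROM1, a marker of bile duct and progenitor cells, at 0.31 ± 0.60, and POU2AF1, a B cell coactivator, at 0.15 ± 0.57. PROM1 ran from 0.20 without pair 2 to 0.43 without pair 4.

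The measured members of the metabolic lists differed little between the time points. Only 4 of 28 drug metabolism members, none of them a cytochrome P450 gene, and 6 of 21 bile acid members had a named probe set. Most of these 2 lists was therefore not surveyed. The 4 measured drug metabolism genes had a mean change of 0.29 ± 0.41 (SD over 9 pairs, higher in 7) and passed camera with the preset correlation (adjusted p = 0.0168), not otherwise (adjusted p = 0.827 with an estimated correlation). After quantile normalization it was at 0.14 ± 0.16 and did not pass (adjusted p = 0.382, camera), nor did it as deposited without pair 4 (adjusted p = 0.144). GSTA2, a glutathione transferase, was at 0.74 ± 0.86, and 1 member was higher when adjusted over the list alone. GSTA2 passed over all genes with array medians subtracted and with an intensity trend and robust variances (adjusted p = 0.000202 at the lowest, limma). The 21 genes of fatty acid and triglyceride synthesis were at -0.02 ± 0.45, a value that passed camera as lower with the preset correlation (adjusted p = 0.0168) and not otherwise (adjusted p = 0.827 with an estimated correlation). After quantile normalization they were at -0.13 ± 0.40 and did not pass (adjusted p = 0.115, camera). As deposited the list did not pass without pair 2 (adjusted p = 0.731, camera) or without pair 10, where its mean turned to 0.10 (adjusted p = 0.685). Within them SCD, the enzyme that makes monounsaturated fatty acids, was at -0.30 ± 0.50 and ACLY, which makes acetyl-CoA for lipid synthesis, at -0.38 ± 0.78, or -0.15 without pair 10. ACACB, an acetyl-CoA carboxylase, and MLXIPL, a carbohydrate-responsive transcription factor, were at 0.29 ± 0.49 and 0.25 ± 0.54. MLXIPL ran from 0.16 without pair 2 to 0.34 without pair 4. Cholesterol synthesis (17 genes) was at 0.08 ± 0.54, with HSD17B7 at 0.32 ± 0.95 and NSDHL at -0.25 ± 0.56. Bile acid synthesis and transport (6 genes) was at 0.06 ± 0.46, with the transporter subunit SLC51B at -0.41 ± 0.57 and the receptor FGFR4 at 0.30 ± 0.62. NSDHL ran from -0.39 without pair 3 to -0.18 without pair 2, and FGFR4 from 0.19 without pair 3 to 0.43 without pair 4. The means of these 2 lists turned after quantile normalization, to -0.03 ± 0.47 and -0.05 ± 0.18. Neither passed with 9 pairs, although cholesterol synthesis passed as higher without pair 2 (adjusted p = 0.00360, camera) and as lower relative to other genes without pair 4 (adjusted p = 0.0445). The camera test of the bile acid list pointed to lower values against a mean above 0. No member of the fatty acid, cholesterol or bile acid lists passed as deposited or after quantile normalization, over all genes or adjusted over the list alone. With array medians subtracted, 1 member of the bile acid list was lower when adjusted over the list alone.

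Lists of cell growth and stress complete the set. The 24 cell division genes had a mean of -0.02 ± 0.49, with a median over members of 0.0003, and passed camera as lower (adjusted p = 0.00930), not with an estimated correlation (adjusted p = 0.827). After quantile normalization the mean was -0.10 ± 0.19. As deposited it ran from -0.11 to 0.10 with 1 pair left out, and camera did not pass without pair 8 (adjusted p = 0.184), with the brightness filter (0.144) or in the 5 pairs with like array medians (0.325). TOP2A, a topoisomerase of dividing cells, was at -0.42 ± 0.92 and TYMS, the thymidylate synthase, at 0.34 ± 0.58. TYMS ran from 0.22 without pair 3 to 0.42 without pair 4. AURKB, a mitotic kinase, was at 0.18 ± 0.70, or -0.05 in the 5 pairs with like array medians. The 17 acute phase and NF-kB genes were at 0.004 ± 0.586 as deposited, where the list did not pass (adjusted p = 0.0718, camera, pointing to lower values). After quantile normalization they were at -0.11 ± 0.16 and passed (adjusted p = 0.00815, camera), although not with an estimated correlation (adjusted p = 0.254). In that list the chemokine gene CCL4 was at -0.44 ± 0.74 and passed after quantile normalization (-0.57 ± 0.38, adjusted p = 0.0373, limma; up to 1.00 over its alternatives), CXCL2 was at 0.48 ± 1.05 and HAMP, which encodes the iron hormone hepcidin, at 0.42 ± 1.79. HAMP turned to -0.10 without pair 8. Endoplasmic reticulum stress genes (11 measured, 0.08 ± 0.57, XBP1 at 0.21 ± 0.52) and immediate early genes (15 measured, 0.06 ± 0.61, FOS at 0.41 ± 1.10, or 0.14 without pair 9) did not pass. Both means turned after quantile normalization, to -0.03 ± 0.12 and -0.04 ± 0.19. Their camera tests pointed to lower values against means above 0. No member of these 4 lists passed as deposited, over all genes or adjusted over the list alone.

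The last comparison asks whether patients differed less in the level of the interferon-stimulated list at the end of treatment. The interferon score, the mean log2 value of the 41 interferon-stimulated genes, was 6.68 ± 0.62 at PRE and 5.73 ± 0.37 at EOT as deposited (SD, n = 9 each). The log2 ratio of the EOT variance to the PRE variance was -1.53, which did not pass an exact 2-sided test that swapped PRE and EOT within the 9 pairs (p = 0.0703). After quantile normalization the score was 6.74 ± 0.418 at PRE and 5.67 ± 0.0738 at EOT, the ratio was -5.01 and the test passed (exact p = 0.00391). The EOT scores then lay between 5.58 and 5.81, below the lowest PRE score of 6.13. As deposited the test also passed without pair 4 (-1.77) and without pair 6 (-1.68), with an exact p of 0.0469 in both cases.

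**Figure D3:**
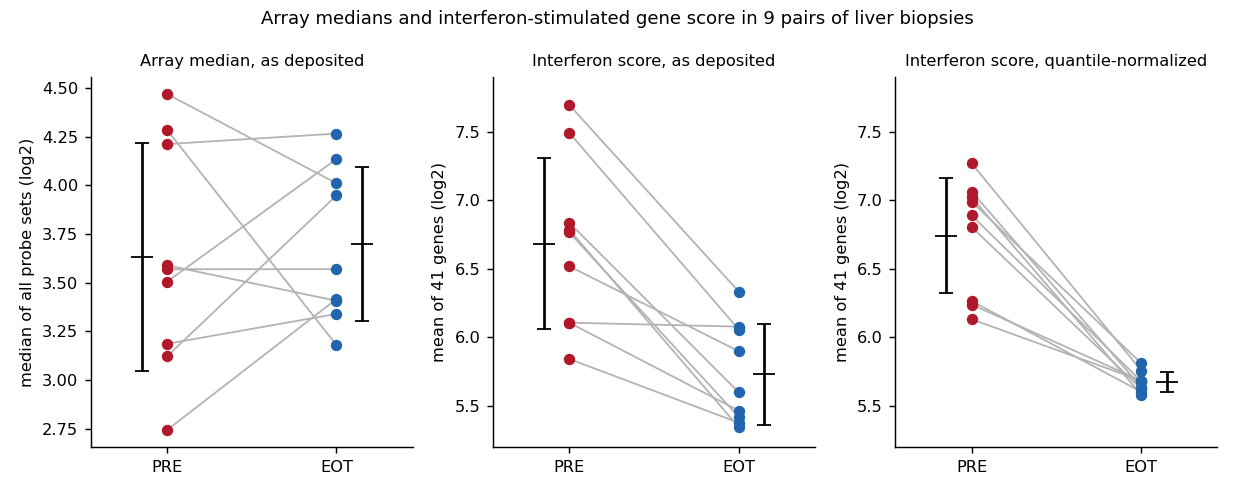
Array medians as deposited and the interferon score (mean of 41 genes, log2) as deposited and after quantile normalization, at PRE and EOT, with lines joining the 9 pairs and bars of mean ± 1 SD. After normalization the EOT scores lie between 5.58 and 5.81 and the PRE scores between 6.13 and 7.27.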

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

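Of the tests in this part, the counts over other splits and the comparison with immune markers were chosen only after the results were seen. The interferon list after quantile normalization was fixed in advance, but its use against array-wide differences was chosen after its value was seen. The 2 tests of the score's spread were written down before their values were known.

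A Dixon gap test of 269 groups of 9 values found 9 with a single value far from the rest, where chance gives about 13.45. ERAP2 was at 3.01 in 1 PRE biopsy, with the next at 5.16. HAMP was at 6.14 in 1 PRE biopsy, with the next at 10.5, and its change was 4.63 in 1 pair, with the next at 1.15. FOS was at 7.82 in 1 EOT biopsy, with the next at 5.55. Changes far from the others were 1.08 for IFNGR1 (next 0.16), -3.39 for EFEMP1 (next -0.81), -2.22 for ACLY (next -0.74) and 1.76 for CD14 (next 0.48). PROM1 was at 2.86 in 1 PRE biopsy, with the next at 3.94.

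Probe sets not named here held signal too. Among 37519 of them, 11 were lower at EOT as deposited and 0 higher (limma, all probe sets tested together), and 58 were lower and 10 higher after quantile normalization. Probe set 16684080 changed by -2.70 ± 1.16 and probe set 16923031 by -2.19 ± 0.78 (SD), both lower in 9 of 9 pairs.

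Other splits that swap PRE and EOT within some of the pairs did not exclude chance for the 30 genes called as deposited: 6 of 100 splits, the real one included, gave as many, and the highest other gave 8719. Splits with several times the real count point to a structure of the samples, and the array medians followed the first principal component (73.7% of the variance). After quantile normalization 1 of 100 splits, the real one, gave 79 genes and the highest other gave 3. Chance is unlikely there but not excluded. The real split is always counted, so 1 of 100 is the smallest share possible, and 100 of the 256 distinct splits were drawn.

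The interferon-stimulated list was lower at EOT in 9 of 9 pairs. Array-wide differences in signal do not account for it alone, since the mean change stayed at -1.07 ± 0.41 after quantile normalization (exact sign-flip p = 0.00391, n = 9). Going by the mean of their markers, a smaller share of T and NK cells and macrophages does not account for it alone either. The list fell by more than these markers in 9 of 9 pairs, with a mean difference of -0.92 ± 0.44 (exact sign-flip p = 0.00391). The markers were not checked for a floor of the arrays. Dim ones, such as CD8B at 3.17 and TRAT1 at 3.59 at PRE, could understate a loss of cells, so the size of this difference is uncertain. The end of treatment, which the design names, stays open as a biological explanation, as do other changes between the biopsies, such as the time elapsed, which were not tested.

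After quantile normalization the interferon score varied less between patients at EOT. A floor of the arrays would narrow dim genes, but the 35 members above the median gene at EOT gave a log2 variance ratio of -4.60 (exact p = 0.00781, 9 pairs). A narrowing of all genes was tested with 10000 random lists matched on EOT level: 0.01% had a ratio as low, with a median of -0.25 and a lowest value of -5.12. The random lists were not matched on how far members vary together or on their spread at PRE. The share therefore cannot tell whether other groups of genes that vary together narrowed too. That the response to infection differs between patients and reaches a common low level at EOT is a hypothesis that may explain the ratio of -5.01 after quantile normalization, for the genes of the score only. The smaller ratio as deposited, -1.53, did not pass, and subtracting only each array's median moved it to -5.11 (exact p = 0.0117, 9 pairs). Genes of the interferon-gamma-induced list, which the score leaves out, went both ways as deposited. From PRE to EOT the SD over biopsies rose for CXCL10 (0.73 to 1.17), CXCL9 (0.73 to 1.29) and CXCL11 (0.68 to 0.79). It fell for GBP4 (0.73 to 0.45), IRF1 (0.77 to 0.44) and ICAM1 (0.62 to 0.26). These differences in spread were not tested.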

How the results depend on the processing

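The array median as a covariate, the 5 pairs with like array medians, quantile normalization with estimated correlations, and the spread with array medians subtracted were chosen after seeing the data. Against 30 genes (4 higher, 26 lower), the fit without the pair block gave 17 (0 higher, 17 lower), quantile normalization 79 (17 higher, 62 lower), subtraction of array medians 52 (14 higher), array weights 67 (15 higher, 52 lower) and the array median as a covariate 58 (14 higher, 44 lower). Higher genes numbered 0 with the pair as a random effect, with all probe sets and in the pairs with like medians, 10 with a trend and robust variances, and 7 at an adjusted p of 0.10. Leaving out 1 pair gave 12 to 35 genes, 0 to 6 higher and 12 to 31 lower, with the low end without pair 4, and 40 to 88 after quantile normalization. The 12 lists called became 2, the interferon lists, with estimated correlations, with fry on the deposited values, and with both quantile normalization and estimated correlations. After quantile normalization fry also called the class I list (adjusted p = 0.00321). The 2 interferon lists kept direction and call under every alternative run, with mean or median changes from -1.21 to -0.79 and from -1.02 to -0.45. Lists gained calls by camera with 1 pair left out: bile duct markers without pair 4 (adjusted p = 0.0445) and pair 10 (0.0239), acute phase and NF-kB genes without pair 1 (0.0277) and pair 4 (0.0184), and cholesterol synthesis without pair 2 (mean 0.13, adjusted p = 0.00360). Without pair 4 cholesterol synthesis was called in the direction opposite to its test over 9 pairs (mean 0.15, adjusted p = 0.0445), and its mean ran from -0.042 to 0.160 with 1 pair left out. The score's log2 variance ratio of -1.53 was -5.01 after quantile normalization, -5.11 with array medians subtracted, and -1.77 to -1.31 with 1 pair left out. The calls of ISG15, DDX60, IFI44L, OASL, HERC5, IFI44 and CXCL11 held under every alternative run. Over all named genes, leave-outs aside, 738 values kept their call, 40 lost it, 31 gained one and 0 reversed. The cause was not tested where a call moved. Signal over background was not analysed here.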

Other observations

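The genes named in this part, the relations with the PRE score and the comparisons of cell markers were chosen only after the results were seen, while the fit after quantile normalization was fixed in advance. The relations with the PRE score replaced an earlier version over all 9 PRE biopsies after its values had been seen.

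Quantile normalization brought out genes outside the fixed lists, 21 lower and 17 higher at EOT. The 6 named here were chosen after their values were seen. LAP3, an aminopeptidase, changed by -0.70 ± 0.22, RNF213, a large ubiquitin ligase, by -0.65 ± 0.34 and SAMHD1, which limits the nucleotides available to viruses, by -0.47 ± 0.30 (log2, SD over 9 pairs). Each was lower in 9 of 9 pairs, with adjusted p of 0.000502, 0.00818 and 0.0429 (limma). ACSM3, a mitochondrial acyl-CoA synthetase, changed by 0.70 ± 0.28, FREM2, an extracellular matrix protein, by 0.70 ± 0.49 and PHGDH, the entry enzyme of serine synthesis, by 0.40 ± 0.22. Each was higher in 9 of 9 pairs, with adjusted p of 0.00136, 0.0360 and 0.0432 (limma). None of these 6 passed as deposited, where their adjusted p was 0.0508 for ACSM3, 0.120 for FREM2 and 1.00 for the others, and each reached 1.00 over its alternatives.

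The PRE interferon scores after quantile normalization were cut at their widest gap, of 0.54, into 3 biopsies from 6.13 to 6.27 and 6 from 6.81 to 7.27. Such a cut always gives 2 groups, and whether the scores form clusters was not tested. As deposited, pair 4 of the lower group scored 6.79, above pairs 2 and 3 of the higher group (6.52 and 5.84). No coefficient over all 9 biopsies is given, a choice that rests on this cut. Over all 9 the relation was positive for the genes lower at EOT and negative for the higher ones, opposite to the signs within the larger group. Within these 6 biopsies, the mean of the 21 lower genes had a Pearson's r of -0.78 with the score (exact permutation p = 0.0611, adjusted p = 0.0611 over 2 relations; Spearman's rho -0.66, exact p = 0.175). The 17 higher genes had r = 0.88 (exact permutation p = 0.0250, adjusted p = 0.05; rho 0.71, exact p = 0.136). Without the 2 biopsies farthest from the median score, r was 0.03 and 0.37, so both relations rest on those biopsies. The adjusted p was made the deciding value after it was seen, and the unadjusted p of the higher genes passes 0.05. With signs that turn on which biopsies are taken, these relations cannot decide whether the genes belong to or oppose the interferon response. Their absence from the fixed lists does not place them outside that response either.

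Markers of T and NK cells and macrophages changed by -0.15 on average after quantile normalization, and the pooled markers of endothelial, bile duct, B and stellate cells by -0.05. These 4 lists went both ways, with endothelial markers at 0.06 ± 0.10 (higher in 6 of 9 pairs), B and plasma cells at -0.01 ± 0.15, bile duct cells at -0.07 ± 0.31 and stellate genes at -0.15 ± 0.24. A smaller share of all cells other than hepatocytes could lower all of these alike. Both immune lists passed camera after quantile normalization with the preset correlation (adjusted p = 0.000681 for T and NK cells and 0.000878 for macrophages). Neither passed there with an estimated correlation (camera, adjusted p = 0.224 and 0.262) or by the exact sign-flip test (adjusted p = 0.123 and 0.174), so no loss is open too. The immune markers differed from the pooled markers by -0.0985 ± 0.156 per pair (exact sign-flip p = 0.0898, lower in 6 of 9 pairs). Against endothelial markers alone the difference was -0.212 ± 0.205 (exact p = 0.0312, adjusted p = 0.125 over the 4 lists, lower in 7 of 9 pairs), which goes against a common loss without excluding it, and against stellate genes it was -0.0016 ± 0.254 (exact p = 0.992). No change, a loss of immune cells and a loss of all cells other than hepatocytes cannot be told apart with 9 pairs.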
